A study of Mus musculus with 3 samples.

How the data were processed

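The measurement was bulk RNA sequencing of adipocyte-containing tissue microdissected from the pancreas of mutant mice aged 8 months. Per the labels' protocols, RNA was isolated with a mirVana kit and strand-specific libraries were made with a NEBNext Ultra Directional kit after removal of ribosomal RNA. Per the submitters' processing notes, the tools named are Trimmomatic 0.38, HISAT2 2.2.1, featureCounts and Subread 2.0.0, with the mouse build GRCm38. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited values are raw counts of reads per Ensembl gene, whole numbers with no normalization, in 1 table of 54532 genes with 1 column per library. No entry of the table lacked a gene, and 25783 genes had at least 1 count in some library. Because a counter either drops or splits reads that fit several copies of a gene, levels of trypsinogens, amylases, alpha and beta globins, the paired insulin genes and Hspa1a and Hspa1b are uncertain.

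Library totals were 40425656, 36218841 and 45245935 counts. Totals of this size make counting error small: an exact Clopper-Pearson 95% interval was computed for each share of counts. A gene without a count was given the upper limit of 3 counts. Reads carry no molecular identifiers, so intervals and limits cover counting error only. Gene symbols and coordinates came from GENCODE mouse release 21 on GRCm38, which holds 54495 of the table's identifiers; the other 37 took 0.00221% of all counts. Of identifiers that share a symbol, the one with the most counts was used.

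All 3 libraries belong to 1 group. The series description speaks of regions of 1 mouse and the sample titles of separate mice, and the labels do not settle which is right. P-values over the libraries concern only these samples and reflect how far the differences within them agree in sign and size. Every pair of libraries was compared first, and no pair agreed within sampling noise, so none was counted as a repeat.

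From the deposited counts, CPM was computed with the library total as the size, and log2(CPM + 0.5) was used for medians of gene lists. Before the data were examined, 26 gene lists with 347 symbols were fixed, covering adipocytes, lipid synthesis, white and brown or beige adipocytes, progenitors and fibroblasts, matrix, acinar, duct and islet cells, immune cells, endothelium, muscle, mesothelium, nerve, erythroid cells, cilia, signalling, proliferation, stress and sex-linked genes. The table lacked 1 symbol, Dnai1, the newer name of Dnaic1, which is in the same list. A member counted as detected at 1 CPM or more in all 3 libraries. The test of 5 list contrasts was an exact two-sided sign-flip permutation test over 3 libraries, with 8 sign patterns and a smallest p of 0.25, and Benjamini-Hochberg adjustment over the 5.

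Differences of single genes between libraries were tested with a Pearson chi-square test of the 3 counts against the library totals (2 degrees of freedom, expected counts of at least 5) with Benjamini-Hochberg adjustment at 0.05. With 1 group there is no contrast for edgeR's quasi-likelihood test, so edgeR served for TMM factors and for the spread: the biological coefficient of variation is the square root of the common dispersion under an intercept-only design after filterByExpr. List ratios between libraries used members with a mean of at least 1 CPM and were set against 10000 random lists drawn from the 100 genes nearest in mean expression to each member; a list below percentile 2.5 or above 97.5 was called outside.

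The chi-square step was tested on simulated Poisson counts for the real genes, with 200 genes changed in 1 library, 20086 genes tested. It recovered 33 of 50 genes changed 1.5-fold, 43 of 50 at 2-fold, 49 of 50 at 4-fold and 50 of 50 at 8-fold. It also called 17 unchanged genes, 8.85% of its calls and more than the nominal share. The real libraries held far more differing genes and a spread beyond counting noise, so these rates do not carry over to them. The step for the coefficient of variation returned 0.2, 0.488 and 0.913 for simulated values of 0.2, 0.5 and 1.

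Genes named in the text were chosen by a rule fixed before the data were examined: up to 4 members of each list with the highest mean CPM, and 18 marker genes whatever their value (Adipoq, Lep, Retn, Pparg, Ucp1, Cidea, Prdm16, Prss2, Cpa1, Amy2a5, Ptf1a, Ins2, Krt19, Sox9, Pdgfra, Adgre1, Pecam1 and Wt1); the 20 genes with the highest mean CPM; and for each library the 4 genes highest and the 4 lowest relative to the mean of the others, among genes with a mean of at least 10 CPM and an adjusted chi-square p under 0.05. Some items that the rule takes are not reported here. Any other gene is said to have been chosen after its values were seen, and C3 is one such gene, named as the most abundant of library 1.

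Alternatives fixed beforehand were a pseudocount of 5 CPM, the mean of a list, detected members only, TPM from the length of merged exons, totals without mitochondrial genes or without the 10 top genes, TMM and DESeq2 size factors, other filters on low counts, DESeq2 dispersions, and leaving out each library in turn. Totals without the acinar and islet genes were added after the data were seen. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. Reads, and with them the mutant alleles and the strain background, were not analysed here.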

Results

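Adipocyte-containing tissue was microdissected from the pancreas of 8-month-old mutant mice and measured by bulk RNA sequencing after ribosomal RNA depletion. The series concerns pancreatic disease in ciliopathies, disorders of the cilium. The labels place all 3 libraries in this 1 group and name no control group, so the values describe the dissected tissue and contain no comparison with healthy pancreas or with normal fat. The series description states that the regions came from 1 mouse, whereas the sample titles number the mice from 1 to 3. The libraries are therefore called library 1, 2 and 3 after the titles, and where libraries share an animal, the p-values over them are too small. The question the design poses is which cell types the dissected regions held, which kind of adipocyte was present, and how far the regions resembled each other.

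The libraries held 40425656, 36218841 and 45245935 counts assigned to genes. At these depths a gene without a count could still have reached 0.0742, 0.0828 or 0.0663 CPM, the usual read count scaled to the library total, in library 1, 2 or 3, the level of 3 counts. Of the 54532 genes in the table, 21025 had a count in library 1, 21571 in library 2 and 22935 in library 3. Mitochondrially encoded genes took 1.89%, 5.37% and 2.93% of the counts. The 10 most abundant genes took 6.15% of library 1, against 28.8% and 25.4% of libraries 2 and 3. The most abundant gene was the complement component C3 in library 1, with 1.34% of the counts, and the chymotrypsinogen gene Ctrb1 in libraries 2 and 3, with 6.84% and 6.62%. Every pair of libraries differed far beyond sampling noise, with a chi-square per degree of freedom of 1452 for libraries 1 and 2, 1519 for libraries 1 and 3 and 264 for libraries 2 and 3. Across 15348 genes with a mean of at least 1 CPM, which are not independent replicates, Pearson's r of log2 CPM was 0.82, 0.82 and 0.92 for these pairs. The biological coefficient of variation between the libraries was 0.499 over 15894 genes (edgeR, n = 3). It was 0.778 with no filter on low counts, and the median of DESeq2 gene-wise estimates was 0.293.

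Because acinar transcripts took a large part of libraries 2 and 3 and little of library 1, the CPM of most other genes was shifted upward in library 1. Over the 15348 genes, the median log2 ratio was 0.72 for library 1 over library 2, 0.79 for library 1 over library 3 and 0.0021 for library 2 over library 3. Scaling by TMM reduced these shifts to 0.02, 0.06 and -0.03. Ratios of gene lists between libraries are therefore given as an excess, which is the median log2 ratio of the list minus the median of 10000 random lists of the same size matched on mean expression, with the percentile of the list among them. With 1 library on each side, an excess describes those libraries and has no replicate check. Random members were drawn independently of one another, whereas members of a list can vary together. A percentile is therefore a description and not a p-value.

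Acinar genes, which encode the digestive enzymes of the exocrine pancreas, dominated libraries 2 and 3 and were scarce in library 1. The 31 acinar genes together took 37.8% of the counts of library 2 (exact Clopper-Pearson 95% interval 37.7 to 37.8) and 32.1% of library 3 (32.1 to 32.1), but 0.483% of library 1 (0.481 to 0.485). All 31 genes were detected at 1 CPM or more in every library and all were lowest in library 1. Ctrb1 reached 1029, 68403 and 66243 CPM in libraries 1, 2 and 3. The pancreatic lipase gene Pnlip stood at 284, 33158 and 22158 CPM, the elastase gene Cela1 at 436, 30242 and 22863 CPM, and the carboxyl ester lipase gene Cel at 178, 26480 and 17019 CPM. The carboxypeptidase gene Cpa1 was at 279, 20247 and 20251 CPM, the trypsinogen gene Prss2 at 164, 16696 and 19375 CPM and the amylase gene Amy2a5 at 5.66, 348 and 237 CPM. Prss2 and Amy2a5 belong to families of near-identical copies, so the split of reads among the copies is uncertain. Ptf1a, the transcription factor that maintains acinar identity, was at 1.24, 8.53 and 4.84 CPM. The excess of the acinar list was -6.59 for library 1 over library 2 and -6.54 for library 1 over library 3, below all 10000 random lists in both cases. Between libraries 2 and 3 it was 0.57, at percentile 99.98.

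**Figure D1:**
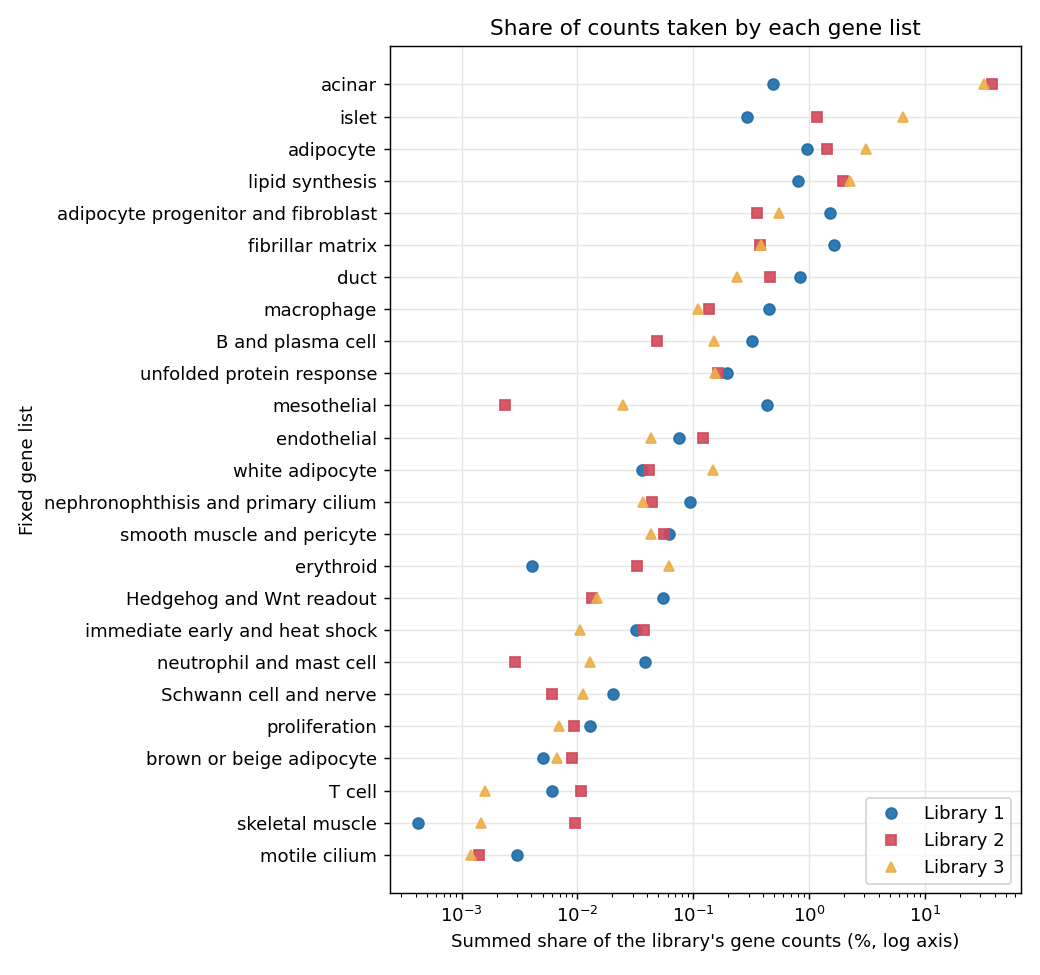
Summed share of each library's gene counts taken by each gene list (x axis, percent, log axis) for the 25 lists on the y axis, with 1 point per library. The acinar list took 37.8% and 32.1% of libraries 2 and 3 and 0.483% of library 1.

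Mature adipocyte genes were well expressed in every library. All 20 members of the adipocyte list were detected in all 3 libraries, and 19 of them were highest in library 3. The list took 0.962% of library 1 (exact 95% interval 0.959 to 0.965), 1.42% of library 2 (1.42 to 1.42) and 3.08% of library 3 (3.08 to 3.09), a mean of 1.82% ± 1.12 (SD, n = 3) that fell to 1.19% without library 3. With acinar and islet genes left out of the total, a denominator chosen after the data were seen, the shares were 0.970%, 2.32% and 5.01%. Car3, a carbonic anhydrase abundant in adipocytes, reached 2802, 4200 and 9008 CPM, and the fatty acid binding protein gene Fabp4 1403, 2090 and 5756 CPM. Cfd, which encodes adipsin, stood at 1211, 1389 and 2700 CPM, and the lipoprotein lipase gene Lpl at 723, 1412 and 1621 CPM. Adipoq, which encodes the adipocyte hormone adiponectin, was at 586, 715 and 1961 CPM, and Pparg, the transcription factor of adipocyte differentiation, at 26.2, 42.2 and 114 CPM. The excess of the list was -1.40 for library 1 over 2, -2.47 for library 1 over 3 and -0.92 for library 2 over 3, at percentiles 0, 0.01 and 0. The 15 genes of lipid synthesis were likewise all detected, 12 of them highest in library 3, with an excess of -1.45, -2.19 and -0.46 for the same pairs (percentiles 0, 0 and 1.68). Among them were the stearoyl-CoA desaturase gene Scd1 with 4945, 12688 and 12701 CPM, the fatty acid synthase gene Fasn with 1005, 3407 and 4207 CPM, Thrsp with 225, 505 and 1321 CPM, and the ATP citrate lyase gene Acly with 365, 561.6 and 744 CPM.

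Within each library, the adipocyte list was set against the acinar list to ask how much exocrine RNA remained beside the fat. The median log2 level of adipocyte genes exceeded that of acinar genes by 1.17 in library 1, but the difference was -3.96 in library 2 and -3.35 in library 3. The mean difference was -2.05 ± 2.80 (SD, n = 3; exact two-sided sign-flip permutation p = 0.5, adjusted p = 0.5), so it was smaller than the spread between libraries. The mean was -3.66 without library 1 and -1.09 without library 2, and -3.76 from TPM. CPM does not correct for gene length, and TPM is given for the mean only. The positive sign in library 1 therefore holds for CPM and may not hold for TPM. With 3 libraries the smallest p this test allows is 0.25, so no contrast could reach 0.05, and p-values over libraries that share an animal are too small.

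The median of the white adipocyte list lay above that of the brown or beige list in all 3 libraries. The difference of the list medians was 3.72 log2 units in library 1, 2.12 in library 2 and 2.99 in library 3, a mean of 2.94 ± 0.80 (SD, n = 3; exact two-sided sign-flip permutation p = 0.25, the smallest possible; adjusted p = 0.5, again too small where libraries share an animal). The mean was 1.87 with a pseudocount of 5 CPM. The lists hold different genes and no normal fat was measured, so the difference also depends on which genes each list holds. Its sign alone does not tell which kind of adipocyte was present. Of the 10 white genes, 7 were detected in every library. Lep, which encodes leptin, stood at 68.0, 105 and 637 CPM, and Retn, which encodes resistin, at 72.0, 140 and 337 CPM. Sncg was at 71.3, 73.6 and 281 CPM and Nnat at 101, 40.1 and 126 CPM. The 3 members not detected were Hoxc8, Hoxc9 and Hoxc10, named after their values were seen; Hoxc8 reached 0.0884 CPM in library 3, and no other count of these genes was seen. Of the 18 brown or beige genes, 10 were detected in every library, at low levels. Ucp1, the uncoupling protein of thermogenic fat, had 0, 2 and 10 counts, which is up to 0.0742 CPM in library 1 and 0.0552 and 0.221 CPM in libraries 2 and 3. Cidea was at 4.77, 3.59 and 2.41 CPM and the brown fat regulator Prdm16 at 9.50, 16.2 and 3.43 CPM. The list's highest member, the potassium channel gene Kcnk3, reached 11.6, 18.03 and 20.7 CPM; Cox8b was at 4.75, 9.001 and 9.50 CPM and Ebf2 at 5.76, 8.14 and 8.04 CPM. The white list had an excess of -1.09 for library 1 over 2, -2.67 for library 1 over 3 and -1.23 for library 2 over 3 (percentiles 0.41, 0.015 and 0.02). The brown or beige list had -1.25, -1.01 and 0.11 (percentiles 0.14, 0.25 and 65.9).

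**Figure D2:**
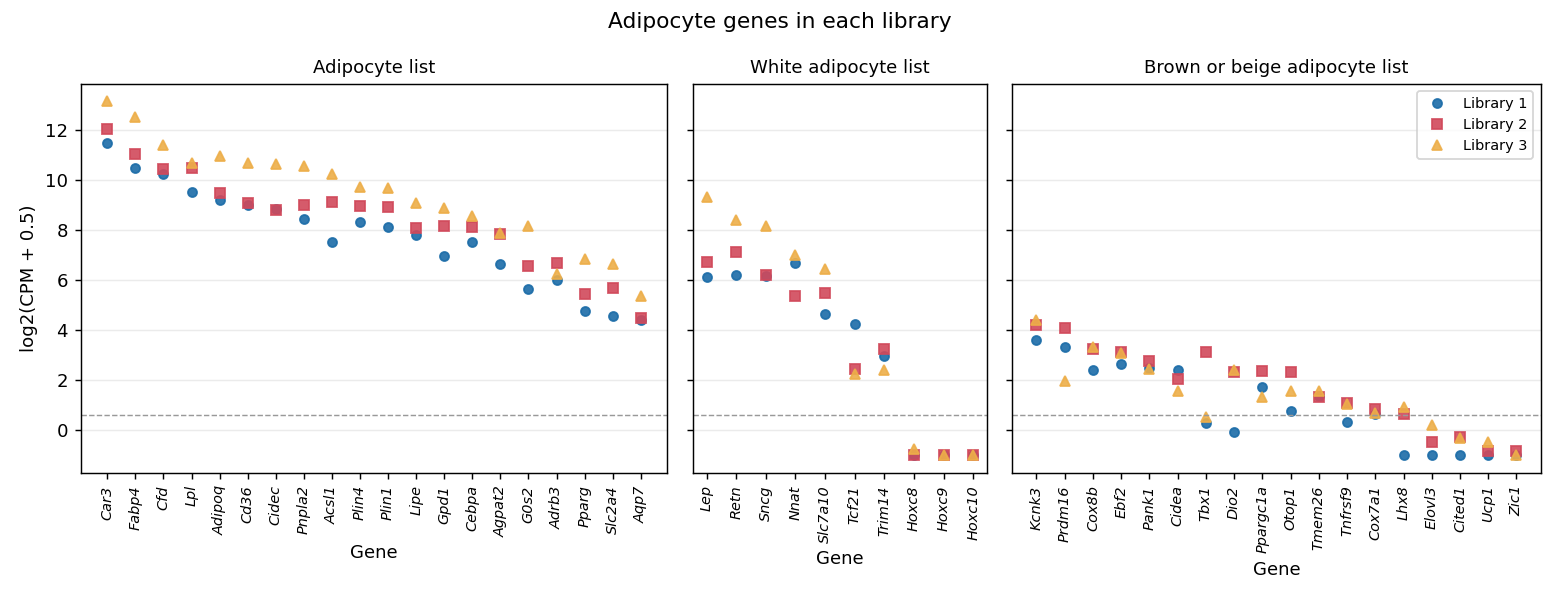
Level of each adipocyte, white adipocyte and brown or beige adipocyte gene (x axis) in each library on the y axis, log2(CPM + 0.5), with a dashed line at 1 CPM. The white gene Lep lies at 68.0 to 637 CPM and the brown fat gene Ucp1 at or under 0.221 CPM, while Hoxc8, Hoxc9 and Hoxc10 of the white list lie at or near 0.

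Genes of adipocyte progenitors and fibroblasts were highest in library 1, where their median lay close to that of mature adipocyte genes. All 16 members were detected, 14 of them highest in library 1. Decorin (Dcn) was at 7435, 372 and 860 CPM, gelsolin (Gsn) at 3010, 1963 and 3574 CPM, Clec3b at 1421, 170 and 221 CPM, Cd34 at 847, 106 and 101 CPM and the progenitor receptor gene Pdgfra at 134, 55.7 and 53.2 CPM. The excess of the list was 0.54 for library 1 over 2 and 0.83 for library 1 over 3, at percentiles 99.3 and 99.85, and 0.10 for library 2 over 3, at percentile 75.4. The difference between adipocyte and progenitor list medians was -0.15 in library 1, 2.72 in library 2 and 3.72 in library 3. Its mean was 2.10 ± 2.01 (SD, n = 3; exact two-sided sign-flip permutation p = 0.5, adjusted p = 0.5, too small where libraries share an animal). It was 3.22 without library 1 and 1.29 without library 3.

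The fibrillar matrix and mesothelial lists were also highest in library 1. All 15 matrix genes were detected, 14 of them highest in library 1, with an excess of 1.34 over library 2 and 1.18 over library 3 (percentiles 99.97 and 99.99), and 0.23 for library 2 over 3 (percentile 94.3). The collagen genes Col3a1, Col1a1 and Col1a2 stood at 6028, 821 and 650 CPM, at 2021, 370 and 410 CPM and at 2094, 363 and 230 CPM, and Sparc, which encodes osteonectin, at 1898, 987 and 1468 CPM. The mesothelial list, genes of the serosal cells that cover abdominal organs, had the largest positive excess of any list, 6.69 for library 1 over 2 and 3.18 for library 1 over 3, above all random lists. It was -3.19 for library 2 over 3, below all of them. The uroplakin gene Upk3b reached 1748, 3.37 and 89.7 CPM, Lrrn4 643, 1.85 and 32.6 CPM, mesothelin (Msln) 527, 6.54 and 38.6 CPM, Gpm6a 466, 3.42 and 29.0 CPM, and the mesothelial transcription factor Wt1 397, 6.71 and 24.6 CPM.

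Duct genes were expressed in every library. The 16 duct genes took 0.825% of library 1 (exact 95% interval 0.823 to 0.828), 0.462% of library 2 (0.460 to 0.464) and 0.237% of library 3 (0.235 to 0.238), and 15 were detected throughout. With acinar and islet genes left out of the total, the denominator chosen after the data were seen, the shares were 0.832%, 0.756% and 0.385%. Clusterin (Clu) was at 3243, 2242 and 582 CPM, the trefoil factor Tff2 at 2145, 784 and 1183 CPM, osteopontin (Spp1) at 1386, 728 and 187 CPM, and Ambp at 232, 216 and 48.4 CPM. Clu, Tff2 and Spp1 made up most of the summed share in each library, and Tff2 is also known from the stomach. The shares are therefore not a measure of duct content alone. The duct keratin Krt19 reached 339, 23.9 and 31.5 CPM; mesothelial cells also express it, and mesothelial genes were highest in the same library. The duct transcription factor Sox9 stood at 58.9, 66.3 and 12.5 CPM. The excess of the list was -0.26 for library 1 over 2 (percentile 9.73), 0.95 for library 1 over 3 (percentile 99.93) and 1.07 for library 2 over 3, above all random lists. Against the acinar list, the duct list differed by 0.50 in library 1, -6.61 in library 2 and -7.81 in library 3. The mean was -4.64 ± 4.49 (SD, n = 3; exact two-sided sign-flip permutation p = 0.5, adjusted p = 0.5, too small where libraries share an animal). It was -7.21 without library 1 and -3.06 without library 3.

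The 27 nephronophthisis and primary cilium genes were all detected in every library, and 25 were highest in library 1. Of all genes at 1 CPM or more, 74.2% were highest in library 1, so the excess sets the list against that background: it was 0.57 over library 2 and 0.62 over library 3 (percentiles 99.98 and 99.96), and 0.12 for library 2 over 3 (percentile 83.6). Markers of other cell types moved with it in library 1: over libraries 2 and 3, the excess was 6.69 and 3.18 for mesothelial genes, 1.34 and 1.18 for matrix genes, 0.54 and 0.83 for progenitor and fibroblast genes, and -6.59 and -6.54 for acinar genes. Glis2 stood at 128, 17.1 and 16.1 CPM, Ift20 at 51.2, 54.0 and 54.6 CPM, Unc119b at 79.9, 39.2 and 32.3 CPM and Dcdc2a at 55.4, 74.7 and 19.2 CPM. The list for Hedgehog and Wnt signalling, pathways that use or neighbour the cilium, had an excess of 0.82 for library 1 over 2 and 1.35 for library 1 over 3 (percentiles 99.65 and 99.97), and 0.26 for library 2 over 3 (percentile 85.7). With no filter on low values, library 1 over 2 was inside the central 95% (percentile 95.7). Its highest members were Smo with 196, 29.9 and 35.96 CPM, Nkd1 with 134, 13.5 and 31.8 CPM, Axin2 with 83.1, 39.5 and 43.7 CPM and Ptch1 with 44.5, 25.0 and 19.8 CPM. Motile cilium genes were low, with Ccdc39 at 13.1, 5.49 and 2.78 CPM, Rsph1 at 8.29, 0.663 and 1.66 CPM, Foxj1 at 2.42, 4.17 and 0.199 CPM and Cfap126 at 2.60, 1.88 and 2.10 CPM. Their excess was 0.29, 0.49 and -0.16 for the 3 pairs, inside the central 95% of random lists each time (percentiles 70.6, 83.8 and 34.9).

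As a list, islet genes were highest in library 3 and lowest in library 1, where both insulin genes were nearly absent. The 24 islet genes took 0.292% of library 1 (exact 95% interval 0.290 to 0.294), 1.16% of library 2 (1.16 to 1.16) and 6.41% of library 3 (6.41 to 6.42); the mean of 2.62% ± 3.31 (SD, n = 3) fell to 0.726% without library 3. Ins2 was at 2.70, 4559 and 32979 CPM and Ins1, its near-identical paralog, at 2.23, 2579 and 15209 CPM. Of the 24, 20 were highest in library 3, and 6 were higher in library 1 than in library 2. Members highest in library 1, named after their values were seen, included Ttr at 688, 380 and 309 CPM, Ppy at 307, 7.45 and 58.8 CPM and Isl1 at 79.8, 10.1 and 24.4 CPM. The glucagon gene Gcg reached 324, 1938 and 6522 CPM and the amylin gene Iapp 54.7, 521 and 3606 CPM. The list's excess was -2.28 for library 1 over 2, -3.93 for library 1 over 3 and -1.56 for library 2 over 3, each below all random lists. Against the acinar list, the islet list differed by -3.39, -7.04 and -5.19 in libraries 1, 2 and 3. The mean was -5.21 ± 1.83 (SD, n = 3; exact two-sided sign-flip permutation p = 0.25, the smallest possible; adjusted p = 0.5, too small where libraries share an animal).

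**Figure D3:**
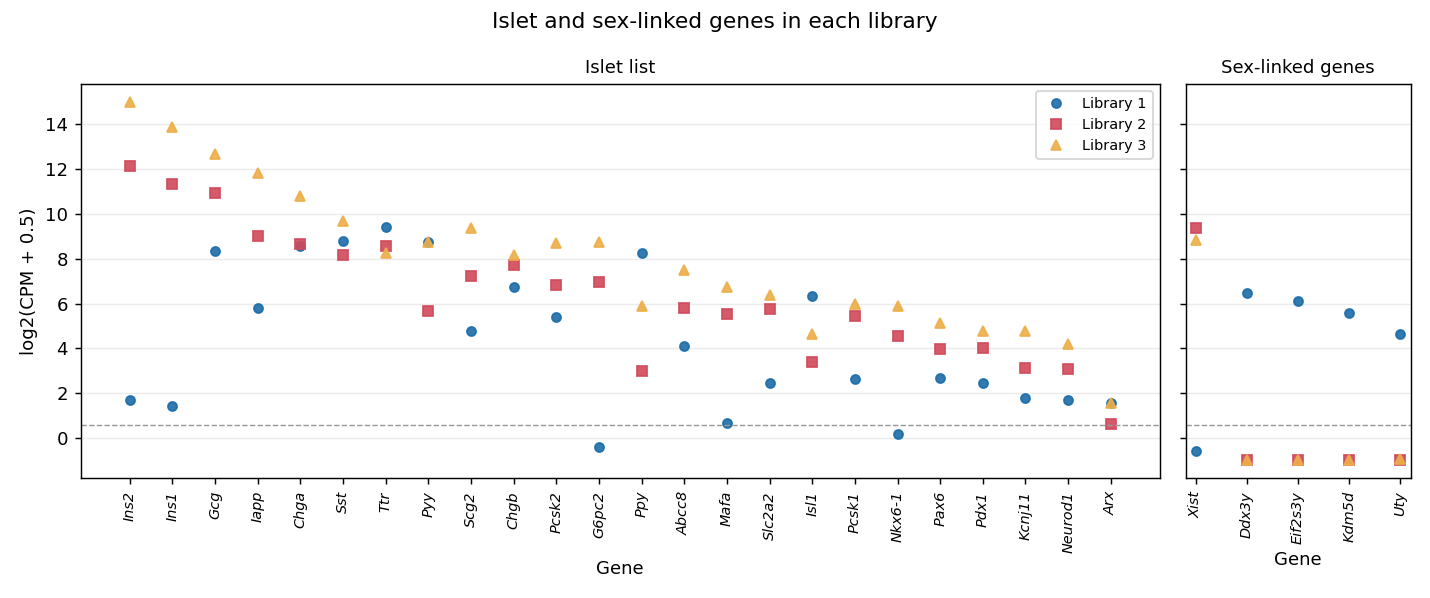
Level of each islet gene and each sex-linked gene (x axis) in each library on the y axis, log2(CPM + 0.5), with a dashed line at 1 CPM. Ins2 lies at 2.70 CPM in library 1 and at 4559 and 32979 CPM in libraries 2 and 3, and the Y-linked genes are expressed in library 1 alone.

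Immune genes were distributed unevenly. Macrophage genes were highest in library 1, with an excess of 0.80 over library 2 and 0.99 over library 3 (percentiles 99.98 and 99.97), and 0.47 for library 2 over 3 (percentile 99.92). All 17 were detected, among them lysozyme (Lyz2) at 1684, 496 and 336 CPM, the complement genes C1qa at 511, 164 and 182 CPM and C1qc at 377, 121 and 101 CPM, Csf1r at 378, 102 and 100 CPM, and Adgre1, which encodes F4/80, at 87.6, 35.5 and 19.98 CPM. T cell genes were scarce. All 10 were higher in library 2 than in library 3, and 8 of 10 were higher in library 1 than in library 3, with Lck at 3.76, 21.8 and 2.98 CPM, Cd3g at 13.8, 12.1 and 0.995 CPM, Cd4 at 10.5, 11.9 and 1.70 CPM and Cd3e at 10.3, 12.3 and 1.06 CPM. Their excess was -1.44 for library 1 over 2 (percentile 0.06), 0.39 for library 1 over 3 (percentile 84.8) and 2.47 for library 2 over 3, above all random lists. B and plasma cell genes had an excess of 1.10, 0.05 and -0.71 for the 3 pairs (percentiles 99.86, 57.3 and 0.28), with the immunoglobulin genes Igkc at 1603, 262 and 535 CPM and Ighm at 799, 103 and 769 CPM, Jchain at 676, 62.8 and 132 CPM and Cd79a at 19.2, 10.5 and 18.6 CPM. The neutrophil and mast cell list was carried by mast cell proteases: Cma1 was at 103, 2.02 and 31.6 CPM, Mcpt4 at 100, 0.166 and 31.8 CPM, Tpsb2 at 82.4, 1.30 and 22.3 CPM and Cpa3 at 66.5, 2.87 and 13.9 CPM. Its excess was 1.78, 0.78 and -2.93 (percentiles 99.96, 98.4 and 0). With no filter on low values, both ratios of library 1 were inside the central 95% (percentiles 51.9 and 90.8).

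Relative to random lists, vascular and muscle genes as lists were highest in library 2. Endothelial genes had an excess of -1.61 for library 1 over 2, below all random lists, -0.22 for library 1 over 3 (percentile 16.5) and 1.501 for library 2 over 3, above all of them. Plvap stood at 224, 355 and 111 CPM, Pecam1 at 99.9, 169 and 57.5 CPM, Kdr at 104, 128 and 41.9 CPM and Flt1 at 48.3, 130 and 31.8 CPM. Smooth muscle and pericyte genes had an excess of -0.89, -0.01 and 1.501 (percentiles 0.07, 48.1 and 100); their highest members were Rgs5 with 208, 217 and 72.6 CPM, Mcam with 55.8, 95.5 and 224 CPM, Acta2 with 79.9, 73.2 and 69.8 CPM and Myh11 with 131, 49.8 and 13.5 CPM. Skeletal muscle genes were low, with an excess of -4.39, -0.53 and 3.34 (percentiles 0, 13.1 and 100); Acta1 was at 0.297, 36.003 and 12.9 CPM, Tnnt3 at 1.26, 22.0 and 0.398 CPM, Myh1 at 0, 18.2 and 0.0442 CPM and Mylpf at 2.498, 9.001 and 1.24 CPM. Erythroid genes, a sign of blood left in the tissue, were lowest in library 1, with an excess of -3.77, -4.56 and -0.97 (percentiles 0, 0 and 0.41). The globin genes Hbb-bs, Hba-a1 and Hbb-bt, which have close copies, reached 18.8, 149 and 311 CPM, 18.03, 144 and 247 CPM and 3.41, 21.8 and 43.8 CPM, and Alas2 reached 0.272, 6.74 and 14.3 CPM. Schwann cell and nerve genes had an excess of 0.53, -0.12 and -0.22, inside the central 95% of random lists for all 3 pairs (percentiles 94.9, 34.0 and 22.5); Mbp was at 154, 36.9 and 41.2 CPM, Th at 3.12, 2.95 and 38.5 CPM and Ncam1 at 9.75, 2.68 and 10.9 CPM.

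**Figure D4:**
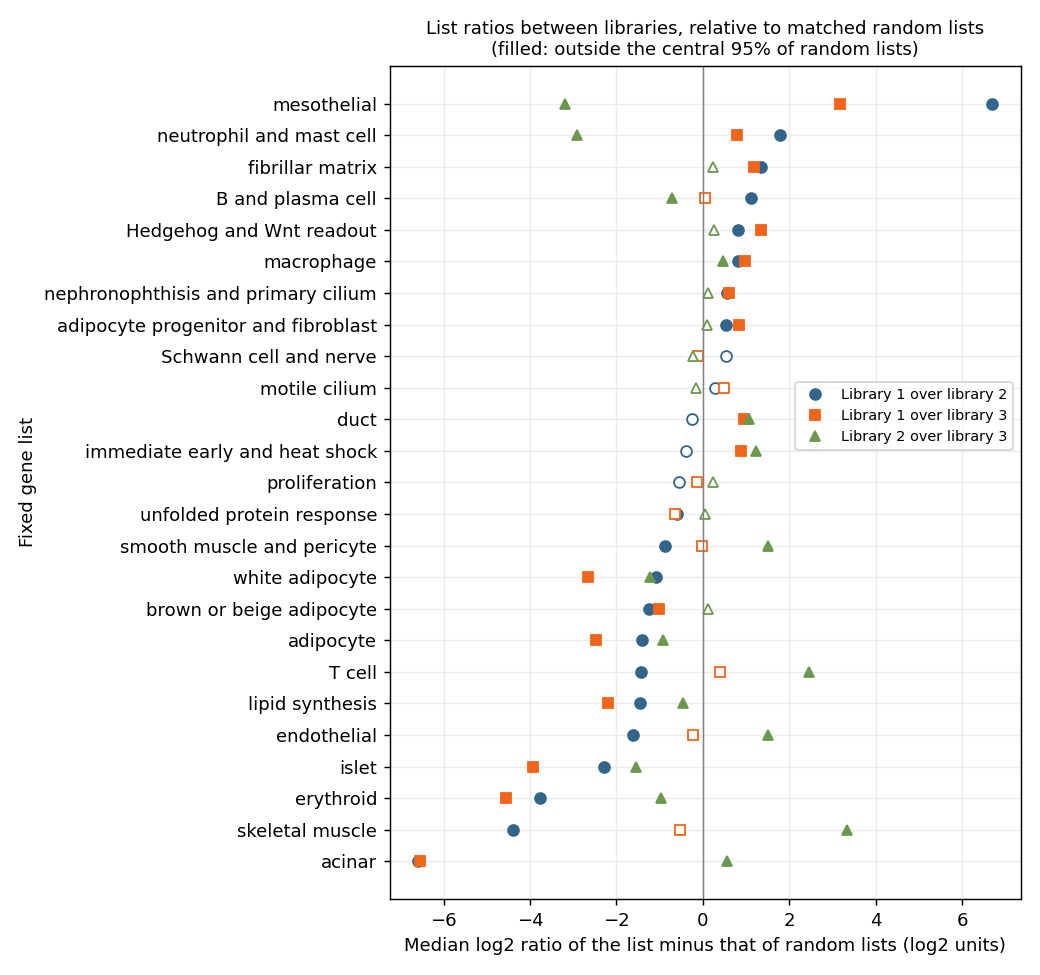
Excess of each gene list (y axis) between pairs of libraries, the median log2 ratio of the list minus that of matched random lists (x axis, log2 units); filled symbols lie outside the central 95% of random lists. The excess of library 1 over library 2 runs from -6.59 for the acinar list to 6.69 for the mesothelial list.

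Among the lists of cell state, proliferation genes stayed inside the central 95% of random lists for all 3 pairs, with an excess of -0.56, -0.13 and 0.22 (percentiles 5.32, 36.4 and 79.9); Pcna stood at 65.0, 38.3 and 32.8 CPM, Mki67 at 14.9, 15.1 and 11.1 CPM, Top2a at 15.1, 13.7 and 5.68 CPM and Rrm2 at 5.19, 7.65 and 5.66 CPM. The unfolded protein response list had an excess of -0.60, -0.65 and 0.04 (percentiles 1.49, 2.70 and 58.0), with the chaperone gene Hspa5 at 868, 645 and 596 CPM, Xbp1 at 354, 313 and 360 CPM, Pdia4 at 256, 107 and 88.0 CPM and Atf4 at 136, 145 and 153 CPM. Its plain log2 ratio of library 1 over 2 was 0.16 with library totals and -0.51 with TMM scaling. Immediate early and heat shock genes, which respond to tissue handling, had an excess of -0.38, 0.88 and 1.23 (percentiles 8.06, 99.64 and 100) and were lowest in library 3 for the members Jun, with 107, 116 and 23.9 CPM, Junb, with 50.4, 67.6 and 14.8 CPM, Ier2, with 30.8, 69.0 and 20.8 CPM, and Egr1, with 19.7, 66.7 and 6.85 CPM. Of the 75 list ratios, 52 lay outside the central 95% of random lists, a count that genes varying together within a list can raise.

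The sex-linked genes separated library 1 from libraries 2 and 3. Xist, which is transcribed from the inactive X chromosome of female cells, was at 0.173 CPM in library 1, from 7 counts, and at 661 and 453 CPM in libraries 2 and 3. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d stood at 87.5, 68.3 and 47.5 CPM in library 1 and had no count in libraries 2 and 3. Uty, the other Y-linked member and named after its values were seen, was at 24.2 CPM in library 1, with no count in library 2 and 1 count in library 3.

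Gene by gene, 18963 of 20074 tested genes differed among the 3 libraries beyond counting noise (Pearson chi-square test per gene with Benjamini-Hochberg adjustment at 0.05). This test compares these libraries and not conditions. Of these genes, 10816 differed by at least 2-fold between the highest and the lowest library and 713 by at least 10-fold, with 0.5 CPM added to each value, which shrinks the ratio of genes near 0. With library totals, 70.3% of the differing genes were highest in library 1, 14.1% in library 2 and 15.7% in library 3; with TMM scaling the shares were 40.0%, 27.9% and 32.0% of 17854 genes. The 20 genes with the highest mean CPM were mostly acinar. Besides Ctrb1, Pnlip, Cela1, Cel, Cpa1 and Prss2, the acinar genes among them were Try4, Cela2a, 2210010C04Rik, Cela3b, Cpb1, Pnliprp1, Clps, Ctrl and Rnase1, with means from 14536 CPM for Try4 down to 6628 CPM for Rnase1. Try4 and 2210010C04Rik are trypsinogen genes whose reads can be shared with Prss2. The others were Ins2, Ins1, Scd1 and the mitochondrial genes mt-Co1, at 8082, 22398 and 11266 CPM, and mt-Cytb, at 3228, 10015 and 5889 CPM.

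Each library also had genes that set it apart. Apart from Ddx3y and Eif2s3y, the genes highest in library 1 relative to the mean of the others were the transcription factor gene Pax1, at 77.3 CPM against 0 and 0.0884 CPM, and the oestrogen sulfotransferase gene Sult1e1, at 133 CPM against 0 and 1.59 CPM. The lowest were Ins2, Ins1, Xist and the amylase copy Amy2a3, at 0.668 CPM against 495 and 510 CPM. In library 2 the highest were the trypsinogen family members Gm5771, at 306 CPM against 0 and 11.3 CPM in libraries 1 and 3, and Prss1, at 48.2 CPM against 0 and 4.27 CPM, together with the antimicrobial lectin gene Reg3g, at 37.0 CPM against 1.41 and 0.707 CPM, and the immunoglobulin gene Ighg2c, at 86.9 CPM against 1.24 and 6.23 CPM. The lowest in library 2 were Upk3b, Pkhd1l1, at 1.41 CPM against 823 and 25.4 CPM, the endocytic receptor gene Lrp2, at 0.0552 CPM against 155 and 5.35 CPM, and the interferon-inducible gene Ifi202b, with no count against 212 and 52.2 CPM. In library 3 the highest, besides Ins2, were Tmem45b, at 84.9 CPM against 0.618 and 1.24 CPM in libraries 1 and 2, the immunoglobulin gene Ighg3, at 57.8 CPM against 0.618 and 0.966 CPM, and Timp4, at 310 CPM against 38.3 and 4.47 CPM. The lowest were Ddx3y, Eif2s3y, Pax1 and Gif, which encodes gastric intrinsic factor, at 0.111 CPM against 243 and 74.6 CPM.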

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

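All 5 list contrasts kept the direction of their mean under every alternative, though none can pass 0.05 with 3 libraries. This concerns the means. Differences in single libraries are given for CPM only, which does not correct for gene length. Leaving out each library in turn gave -3.66 to -1.09 for adipocyte minus acinar, 2.56 to 3.36 for white minus brown or beige, 1.29 to 3.22 for adipocyte minus progenitor, -7.21 to -3.06 for duct minus acinar and -6.11 to -4.29 for islet minus acinar. The mean shares ran from 1.19% to 2.25% for adipocyte, 16.3% to 34.9% for acinar, 0.349% to 0.644% for duct and 0.726% to 3.79% for islet genes. The count of differing genes ran from 13584 to 17737 and the coefficient of variation from 0.396 to 0.544. The 5 contrasts pair lists within each library, and no pairing of samples across groups was possible because the libraries form 1 group.

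The number of differing genes was 10072 when only the 10175 genes with a mean of at least 10 CPM were tested, fewer because fewer were tested. The coefficient of variation was 0.778 with no filter on low counts and 0.293 as the median of DESeq2 gene-wise estimates, which is a different summary of the spread; the cause of the first was not tested. The unfolded protein response ratio of library 1 over 2, 0.16 with library totals, was -0.51 with TMM, -0.54 with DESeq2 size factors and -0.49 with totals without acinar and islet genes, a setting added after the data were seen; each removes the shift of all genes, and its excess over random lists was negative in all of them. Of the 52 list ratios outside the central 95%, all stayed outside with TMM, DESeq2 factors, a pseudocount of 5 CPM and totals without acinar and islet genes. With no filter on low values, 49 stayed outside. The 3 lost were neutrophil and mast cell for both ratios of library 1, and Hedgehog and Wnt for library 1 over 2. Their plain log2 ratios were 0.60 (library 1 over 2), 1.01 (library 1 over 3) and 1.11. These ratios changed because members with a mean under 1 CPM joined the lists. The pool of random lists also widened, and its part in the percentiles was not tested. The unfolded protein response ratio of library 1 over 3 (0.13) moved outside. With a mean of at least 10 CPM, 60 ratios could be computed; 46 stayed outside and the immediate early ratio of library 1 over 2 (-0.12) joined them. No excess outside the central 95% changed sign.

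Totals without the 10 top genes moved the mean share of smooth muscle genes to 0.0654% and of unfolded protein response genes to 0.209%, beyond 1 SD. Totals without acinar and islet genes moved those to 0.0745% and 0.238%, and lipid synthesis to 2.54%, brown or beige to 0.0102% and proliferation to 0.0131%, as a smaller denominator must. Depth limits only genes near 0 counts, such as Ucp1.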

Other observations

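Of the tests below, those of gut tissue and of a pyloric gland program were written before their result was seen, and all the others after. The repeat of the pyloric gland test with TMM scaling and its comparison with chance were also added after. The patterns were found by reading the genes most extreme in each library and those on in one of libraries 2 and 3 and off in the other, so every gene named here outside the fixed lists was chosen after its values were seen.

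In library 1, where the fibroblast, matrix and mesothelial lists were highest, some genes outside the lists were also high. C3 stood at 13445 CPM against 1214 and 2147 CPM in libraries 2 and 3, the complement gene C7 at 159 CPM against 0.884 and 7.01 CPM, Igfbp6 at 3097 CPM against 56.4 and 179 CPM, fibromodulin (Fmod) at 1016 CPM against 7.81 and 32.9 CPM, and the B cell chemokine Cxcl13 at 190 CPM against 2.24 and 35.5 CPM. Library 2 had the highest levels of the regenerating genes Reg3a and Reg3b, at 16.95 and 80.9 CPM, against 0 and 0.297 CPM in library 1 and 3.58 and 9.02 CPM in library 3. Reg2 was at 0.643, 135 and 91.1 CPM and Reg3d at 1.31, 95.9 and 72.1 CPM in libraries 1, 2 and 3. The antigen presentation genes H2-Aa, H2-Ab1 and H2-Eb1 were at 508, 493 and 403 CPM in library 1 and 543, 584 and 480 CPM in library 2, and 177, 155 and 144 CPM in library 3; with TMM scaling they were at 360, 349 and 286 in library 1, 637, 686 and 563 in library 2, and 213, 186 and 173 in library 3. The checkpoint receptor gene Pdcd1 was at 1.04, 3.95 and 0.133 CPM in libraries 1, 2 and 3. The oxytocin receptor gene Oxtr stood at 17.3, 28.9 and 188 CPM and the beta cell zinc transporter gene Slc30a8 at 3.17, 24.5 and 78.5 CPM.

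The sex-linked genes argue against 1 mouse as the source of all 3 libraries: 4 of 4 Y-linked genes were at 10 CPM or more in library 1 and without a count in library 2, with 9199, 0 and 1 Y-linked counts in libraries 1, 2 and 3. A mixture of male and female tissue within a library is argued against too, since the highest trace of the other sex was 0.0382% of the level in the other libraries. Whether libraries 2 and 3 share an animal cannot be told apart from a difference in cell makeup: Trim12a was at 9.30 CPM in library 2 and 0.0442 CPM in library 3, yet 1 other gene, the muscle gene Myh1, showed as wide a gap. Trim5, beside it on chromosome 7, was at 11.2, 6.24 and 0 CPM, and interferon-inducible genes clustered on chromosome 1 also parted, with Ifi202b at 212, 0 and 52.2 CPM, Mndal at 10.6, 55.1 and 1.75 CPM and Ifi206 at 0.247, 7.43 and 0.0221 CPM, which may reflect a mixed strain background. An exchange of library 1 with a sample from outside the group was not tested and stays open, as does sex as a source of other differences between the libraries.

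The endocrine genes of library 1 differed in their proportions from those of libraries 2 and 3. Ppy and the ghrelin gene Ghrl were highest in library 1, at 307 and 41.1 CPM, against 7.45 and 0.635 CPM in library 2 and 58.8 and 1.26 CPM in library 3. They stayed highest there with TMM scaling. Pyy was at 425, 50.6 and 428 CPM and Sst at 438, 283 and 816 CPM in libraries 1, 2 and 3. With TMM scaling, Pyy was at 301, 59.4 and 514 and Sst at 310, 333 and 980, so Sst was then lowest in library 1. A proportional loss of islet cells of every type is argued against by the ratio of Ins2 to Gcg, 0.00833 in library 1 against 2.35 and 5.06. Gut tissue of the kinds that the listed genes mark is argued against in the dissected piece. The median of 17 gut epithelium genes was 0 CPM and only 1, Pgc, reached 10 CPM, and of 8 gut endocrine genes the highest, Tph1, was at 3.22 CPM. This does not cover Brunner's glands of the duodenum. Whether beta cells were lost or were present with some genes low cannot be told from 10 other beta cell genes, taken relative to Gcg in library 1. Their median was 0.489 times library 2 and 0.507 times library 3, with 5 of 10 under 0.5 times each. They went both ways, from Ucn3, without a count in library 1, to Pdx1 at 1.89 and 3.72. The first 5 genes tried (G6pc2, Mafa, Nkx6-1, Ucn3 and Glp1r), whose medians were 0.144 and 0.204, were a narrower choice. G6pc2 had 10, 4535 and 19289 counts and Ucn3 0, 645 and 4236 counts in libraries 1, 2 and 3. The low level in library 1 was thus not limited to the insulin genes. Some of the 10 genes are also expressed in other islet or duct cells, and a wider loss of beta cell identity and a different part of the pancreas stay open as hypotheses, untested.

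Some genes usually known from the stomach were higher in libraries 1 and 2 than in library 3: the pepsinogen gene Pgc was at 1364, 834 and 25.6 CPM, Gif at 243, 74.6 and 0.111 CPM and Pga5, low in library 1, at 7.69, 37.2 and 0.265 CPM, whereas Tff2, at 2145, 784 and 1183 CPM, was lowest in library 2. Stomach tissue in the dissected piece is argued against, because the highest of 6 pit and parietal cell genes in library 1 (Atp4a) was at 1.88 CPM. A gland program like that of the pylorus in pancreatic cells could not be decided. In library 1, 4 of 4 genes of that program were at 10 CPM or more and higher than in library 3, with CPM and with TMM scaling. Of all genes at that level, 88.0% and 57.5% were also higher. The prediction written beforehand asked only for this level and direction and was met. A comparison with chance was added later. By direction alone, 4 of 4 would arise by chance with p = 0.109 (binomial, TMM). That is the smallest p that 4 genes allow at this background, so the comparison could not have decided the question. They were Gkn3 at 2350, 258 and 292 CPM, Muc6 at 1224, 225 and 409 CPM, Aqp5 at 103, 36.003 and 16.9 CPM and Wfdc2 at 19.3, 8.17 and 4.91 CPM. TMM scaling nearly removes the shift of all genes in library 1. With it, libraries 1 and 3 stood at 1666 and 351 for Gkn3, 868 and 491 for Muc6, 72.9 and 20.3 for Aqp5, and 13.7 and 5.90 for Wfdc2. The shift alone therefore does not account for these 4 differences, each from 1 library against 1. Muc6 and Gkn3 were lower in library 2 than in library 3, unlike Pgc and Gif, so these genes do not move as 1 set. Normal duct glands and Brunner's glands of the duodenum were not tested and stay open, and without control pancreas the pattern cannot be tied to the mutation.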
